A study of Mus musculus with 21 samples.

How the data were processed

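Total RNA from 6 mouse cell lines was converted to biotinylated cRNA and hybridised to Illumina MouseWG-6 V2 bead arrays, 1 array per hybridisation and 21 arrays in all. The lines were MEF (4 arrays), ES (3 arrays), NS (3 arrays) and the induced neural stem cell clones iNS2 (3 arrays), iNS3 (4 arrays) and iNS5 (4 arrays). The arrays lay on 4 slides. Slide 1 held MEF replicates 1 to 3, and slide 2 held iNS2 and iNS3 replicates 1 to 3. Slide 3 held all ES arrays and iNS5 replicates 2 to 4. Slide 4 held all NS arrays, MEF replicate 4, iNS3 replicate 4 and iNS5 replicate 1. Thus iNS2 shared no slide with MEF, NS, ES or iNS5, and ES shared none with MEF or NS. The series text calls the arrays of a line technical replicates. The p-values of comparisons between arrays therefore measure only technical spread. Only the comparisons of the clones as a group cover separately derived lines, and no line has separate cultures or animals.

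The deposited scanner table gives the intensity of each probe on each array as the mean bead signal, on a linear scale and with background included. Per the file headers, a second column for each array holds the detection p-value, the share of negative control beads at or above the probe's signal. The authors also deposited a scaled intensity table on the linear scale. Each of its columns was a straight-line function of that array's scanner signal, with a largest residual of 0.1148, so background was subtracted and 1 factor per array brought every column to a mean of 379.2. The column medians of that table lay between 6.7 and 8.3. Its scale is thus known from the values, no centring across arrays was found, and the settings behind its background step are unknown. The submitters' processing notes name GenomeStudio, and its version was not given. Of 45281 probes, 34885 carried 1 gene symbol, 18 several and 10378 none. Gene identifiers of 34807 probes were matched to the mouse reference annotation, and 0 symbols changed. All 21 value columns were matched to a line, and 0 were left over.

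A probe counted as well above background on an array where its detection p-value was under 0.01. Between 14407 and 16021 probes per array passed, and the median scanner signal per array lay between 127 and 168.5. The number of arrays and of clones limits the precision. Scanner intensities were background corrected and quantile normalised with neqc in limma 3.58.1 under R 4.3.3, with controls inferred from the detection p-values and an offset of 16, and put on the log2 scale. Tested probes carried 1 symbol and were well above background on every array of at least 1 line, which left 15972 probes. The probe with the highest mean over all arrays stood for its gene, which gave 10449 genes. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.

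Comparisons between lines (ES, NS, iNS2, iNS3 and iNS5 against MEF, and the pairs of clones) used 1 limma fit of all arrays with 6 groups and 15 residual degrees of freedom. Changes were tested with treat against a 2-fold change and called at a Benjamini-Hochberg adjusted p under 0.05. Comparisons of the clones as a group with MEF, NS or ES used 1 mean profile per line, with the 3 clones as replicates and 2 residual degrees of freedom. The single line on the other side was assumed to vary like the clones. These were tested with eBayes in limma against no change, two-sided, at the same adjusted p. Standard errors are of log2 differences and come from these fits. Where a gene was well above background on no array of one side, its fold is given as at least the ratio to the dimmest detected probe of those arrays, and no fold is given where both sides were at background. Where only some arrays of the dimmer side were well above background, each of its arrays was set at no less than that floor, which was chosen after the values were seen.

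For each gene called between NS and MEF, the position of another line was its distance from MEF as a share of the NS to MEF distance, and a position over 0.5 counted as nearer to NS. Because the comparisons with MEF share the MEF arrays, overlaps of calls were set beside the overlap of independent lists, beside 20 simulated data sets of unchanged lines against the same MEF arrays, and beside splits of the MEF arrays. The 21 gene lists were neural stem and radial glia, fibroblast and mesenchyme, pluripotency, neuronal, astrocyte, oligodendrocyte lineage, forebrain regional, midbrain and hindbrain regional, Hox clusters, cell cycle, cell cycle inhibitors and p53 targets, epithelial, endoderm with mesoderm and trophoblast, imprinted, interferon response, myeloid and lymphoid, endothelial, muscle, glycolysis and hypoxia, cholesterol synthesis, and sex-linked. They were tested with camera at a preset correlation of 0.01, adjusted over 105 tests in 5 comparisons, and again with an estimated correlation. The estimated form tests on the residual degrees of freedom of the fit, 2 for the clones and 15 for the arrays. With 2, no list was called in any clone comparison, so a call lost there does not by itself speak to correlation between genes. For the fibroblast list against MEF the estimate was 0.009, below the preset value, as it was for neural stem and radial glia (-0.03) and Hox clusters (0.009). It was above the preset value for cell cycle (0.332), cholesterol synthesis (0.304), interferon response (0.16) and glycolysis and hypoxia (0.671). For those lists the camera p-values of the clone comparisons may be too small. The 15 rest on technical spread. A median with bounds sets members that were undetected on one side at their smallest possible change.

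The lists, groups, tests of the comparisons, most alternatives and the rule for naming genes were fixed before the data were examined, and what was added later is said to be so where it is used. Among called genes whose arrays or clones did not overlap the other side, that rule took those with the largest rise and fall among genes measured on all arrays of both sides. It also took the brightest genes detected on one side alone, up to 4 called members of each list or up to 2 uncalled members where none was called, and Pou5f1, Sox2, Klf4, Myc and Nanog in every line. Symbols of unnamed transcripts were counted, not named. Alternatives covered the background step, the offset, median scaling, the authors' scaled table, the detection filter, the mean of all probes, an intensity trend, the 2-fold threshold, the slide as a fixed or random block, single slides, other set tests and leaving out each array or clone. On simulated data, the fit of NS against MEF found 80.6% of genes changed by 1.5 on the log2 scale, 98.51% at 2 and 100% at 3, with 0 false calls. The fit of the clones against NS found 56.72% at a log2 change of 2, 68.66% at 3 and 87.88% at 5, with 4 false calls among 10449 genes. A line simulated at position 0.7 gave a median of 0.7, and a shifted list was called along with 1 list that had not been shifted.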

Results

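Gene expression was measured on 21 arrays from 6 mouse cell lines. MEF are embryonic fibroblasts that carry an Oct4 reporter, and iNS2, iNS3 and iNS5 are clones numbered 2, 3 and 5 that were converted from such fibroblasts into neural stem cells. NS are neural stem cells grown from mouse forebrain, and ES are embryonic stem cells. The source label of the 3 ES arrays repeats the fibroblast source, and they were taken as ES from their other labels and from bright Nanog, Pou5f1 and Dppa5a. The series asks whether fibroblasts can be turned directly into neural stem cells that keep dividing in culture. Between 14407 and 16021 of 45281 probes per array were well above background. Across genes, arrays of a line correlated at 0.993 or more, and genes are not independent replicates.

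The line profiles fell into a neural stem cell group, MEF and ES. Across 10449 genes, the mean profiles of the clones correlated with NS at 0.977 (iNS2), 0.975 (iNS3) and 0.970 (iNS5), and with one another at 0.967 to 0.984. Their correlation with MEF was 0.685, 0.693 and 0.687, and with ES 0.743, 0.737 and 0.734, in the same order. The median SD between the clone means was 0.198 on the log2 scale, against a residual SD between arrays of 0.13.

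**Figure D1:**
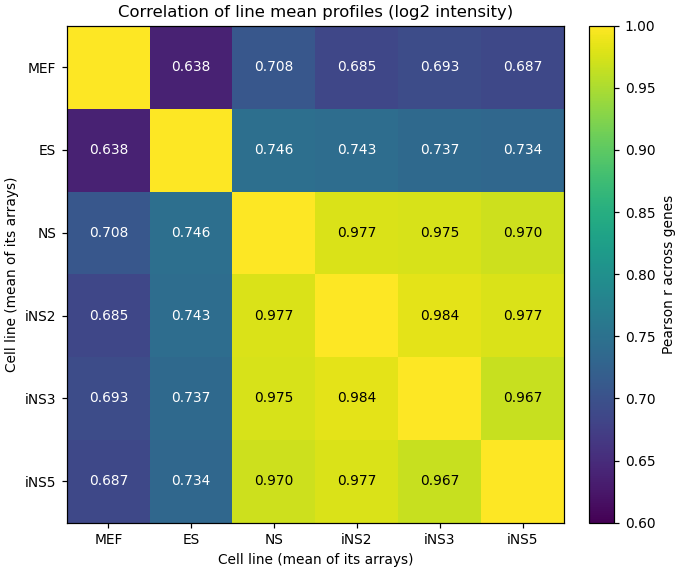
Pearson correlation across 10449 genes between the mean log2 intensity profiles of the 6 lines, with the value in each cell. NS and the clones lie between 0.967 and 0.984 of one another, and the correlations of the clones with MEF lie between 0.685 and 0.693.

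The clones were set against MEF to ask how far the converted lines differed from the cells they came from. Olig1, a transcription factor of glial and neural progenitors, was at least 590-fold higher in the clones than in MEF, where it was not well above background (log2 difference 10.01 ± 0.17 SE, 11 arrays of 3 clones against 4 MEF arrays, limma adjusted p = 3e-04). Sox21 and Rfx4, transcription factors of neural progenitors, and Bcan, a brain proteoglycan, were at least 130-fold, 81.6-fold and 61.4-fold higher, again with no MEF array well above background. Bgn, an extracellular matrix proteoglycan, was at least 794-fold lower in the clones (log2 difference -10.48 ± 0.17 SE, adjusted p = 3e-04). Lox, which crosslinks collagen, Thbs2 and the fibroblast surface marker Thy1 were at least 725-fold, 710-fold and 679-fold lower, and none of these 4 genes was well above background on any clone array.

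Among genes measured on all arrays of both sides, Aldoc, a glycolytic enzyme abundant in astrocytes, was 85.6-fold higher in the clones (log2 difference 6.42 ± 0.43 SE, adjusted p = 0.0013). The imprinted gene Mest was 80.4-fold higher, Smoc1 59.8-fold, the histone genes H2ac12 and H2ac15 55.8-fold and 54.5-fold, the endothelin receptor gene Ednrb 54.2-fold and Chst7 53.9-fold. The brightest probe of Bex2 was at least 178-fold higher and not well above background in MEF, where another of its probes was. Bcas1, Nup210 and Rtn1 were at least 150-fold, 145-fold and 134-fold higher, with MEF not well above background. On the other side, Igfbp7 was 150-fold lower in the clones (log2 difference -7.23 ± 0.44 SE, adjusted p = 0.0011), Cemip 117-fold, Lgals3bp 104-fold and Rai14 101-fold. Txnip, the collagen genes Col4a2 and Col6a1, and the cytokine receptor gene Osmr were 84.3-fold, 78.3-fold, 76.7-fold and 71.5-fold lower. Saa3, an acute phase gene, was at least 738-fold lower and not well above background in the clones.

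Of the neural stem and radial glia list, 21 of 27 tested members rose in the clones, 2 fell and 4 did not pass (21 and 3 adjusted over the list alone). The list's median log2 change was 3.64, or 2.99 with bounds (camera adjusted p = 6.6e-06, and adjusted p = 0.15 with an estimated correlation). Of the fibroblast and mesenchyme list, 33 of 34 members fell and 1 did not pass (34 adjusted over the list alone), with a median of -5.87, or -5.49 with bounds (camera adjusted p = 1.7e-17, and adjusted p = 0.076 with an estimated correlation). Of the cell cycle list, 23 of 26 members rose and 3 did not pass (24 higher and 1 lower adjusted over the list alone), with a median of 3.07, or 3.02 with bounds (camera adjusted p = 5e-09, and adjusted p = 0.45 with an estimated correlation). Aurkb, a mitotic kinase, was 17.1-fold higher, Nusap1 16.6-fold, the replication factor Mcm5 13.7-fold and Cdc20 13.4-fold.

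Interferon response genes were lower in the clones: 24 of 25 fell and 1 did not pass (24 adjusted over the list alone), with a median of -4.01, or -3.97 with bounds (camera adjusted p = 3.6e-10, and adjusted p = 0.32 with an estimated correlation). Isg15, a ubiquitin-like protein induced by interferon, was at least 314-fold lower (log2 difference -8.66 ± 0.76 SE, adjusted p = 0.0025), and of the 11 clone arrays only the 4 of iNS5 were well above background. Ifit3 was at least 344-fold lower with 6 clone arrays above background, and Usp18 and Oasl2 at least 213-fold and 106-fold with 4. Of the cholesterol synthesis list, 12 of 17 members rose and 5 did not pass (14 adjusted over the list alone), with a median of 1.72, or 1.60 with bounds (camera adjusted p = 3e-04, and adjusted p = 0.51 with an estimated correlation). Dhcr7 was 5.48-fold, Pmvk 5.38-fold and Fdps 4.95-fold higher, and Idi1 at least 2.82-fold, with MEF not well above background.

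Of the Hox clusters, which pattern the body axis, 14 of 21 tested members fell, 2 rose and 5 did not pass (15 lower and 3 higher adjusted over the list alone). Their median was -2.20, or -1.59 with bounds (camera adjusted p = 5.4e-05, and adjusted p = 0.20 with an estimated correlation). Hoxc6, Hoxc9, Hoxb7 and Hoxb2 were at least 144-fold, 38.6-fold, 36.9-fold and 17.9-fold lower in the clones, where none was well above background on any array.

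Among lists that camera did not call against MEF, the pluripotency list had 3 members higher, 6 lower and 23 not passing (3 and 6 adjusted over the list alone), and its median of 0.05 differed in sign from its mean of -0.33. Sox2, which serves both pluripotent and neural stem cells, was at least 19.1-fold higher, Lefty1 was at least 11.4-fold lower, the brightest probe of Tbx3 at least 19.7-fold with another probe above background on 1 of 11 clone arrays, and Klf2 at least 8.95-fold with 4. Neuronal genes were higher in 5 of 12 cases and lower in 1 (5 and 1 adjusted over the list alone), among them Map2, which was at least 135-fold higher with 2 of 4 MEF arrays above background, and Syp, at least 4.35-fold. Astrocyte genes were higher in 6 of 15 cases and lower in 1 (6 and 1 adjusted over the list alone), with the glutamate transporter gene Slc1a3 33.5-fold higher and Nfia at least 15-fold, the latter with 3 of 4 MEF arrays above background. Without the detection filter, camera called the astrocyte list higher (adjusted p = 0.0145). Of 12 oligodendrocyte lineage genes, 4 rose and 2 fell (4 and 2 adjusted over the list alone). Sox8 and Olig2 were at least 21.9-fold and 8.22-fold higher, and Pdgfra was 50.4-fold lower. Of 5 forebrain genes, Otx1 (at least 25-fold) and Lhx2 (at least 1.08-fold) rose (1 adjusted over the list alone). Lhx2 was above background on 8 of 11 clone arrays and on no MEF array. Of 6 midbrain and hindbrain genes, Gbx2 rose by at least 6.62-fold and En1 was at least 43.7-fold lower with 7 of 11 clone arrays above background (0 higher and 1 lower adjusted over the list alone).

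Of 17 cell cycle inhibitors and p53 targets, 3 rose and 6 fell (3 and 7 adjusted over the list alone). Cdkn2c was 9.79-fold higher and Gadd45b at least 8.97-fold lower, the latter with 9 of 11 clone arrays above background, while Cdkn1c was at least 41.4-fold lower with 5 clone arrays above background. Of 21 imprinted genes, 4 rose and 10 fell (4 and 10 adjusted over the list alone), with Igf2 at least 52.9-fold lower and 6 clone arrays above background. The brightest probe of Grb10 was at least 151-fold lower, and another of its probes was above background on 1 clone array. Of 14 epithelial genes, 3 fell (3 adjusted over the list alone), namely Cdh3 by at least 16.5-fold, Spint1 by at least 1.42-fold and Esrp2 by at least 1.16-fold. The brightest probe of Esrp2 was above background on 1 of 4 MEF arrays and on no clone array. The other probe of Spint1 that passed the detection filter was at 0.04 on the log2 scale. Of 3 endoderm, mesoderm and trophoblast genes, Gata6 fell, at least 9.39-fold (1 adjusted over the list alone). Of 4 myeloid and lymphoid genes, Laptm5, Lyz2 and Cd14 fell (3 lower and 1 higher adjusted over the list alone), and of 7 endothelial genes Eng fell, at least 3.44-fold (1 adjusted over the list alone). Of 8 muscle genes, 4 fell, among them Acta1 by at least 13.8-fold, and Mef2c was 7.25-fold higher (5 lower and 1 higher adjusted over the list alone). Of 21 glycolysis and hypoxia genes, 3 fell and 1 rose (1 lower and 0 higher adjusted over the list alone), with the brightest probe of P4ha2 at least 138-fold lower and above background on 4 of 11 clone arrays. Of the 4 sex-linked genes, Eif2s3y was 5.42-fold higher, Kdm5d at least 2.97-fold higher and Xist at least 12.4-fold lower (2 higher and 1 lower adjusted over the list alone). In MEF, both Xist and Eif2s3y were well above background on all 4 arrays. The sex of the source cells could give these differences, which are not read as effects of conversion.

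In all, 2491 genes rose and 2421 fell between MEF and the clones, and 4039 of these 4912 changes were at least 2-fold. Without clone 2 the count was 2719, and on the single slide that held NS, with clones 3 and 5 and an alternative chosen after seeing the data, it was 2727.

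**Figure D2:**
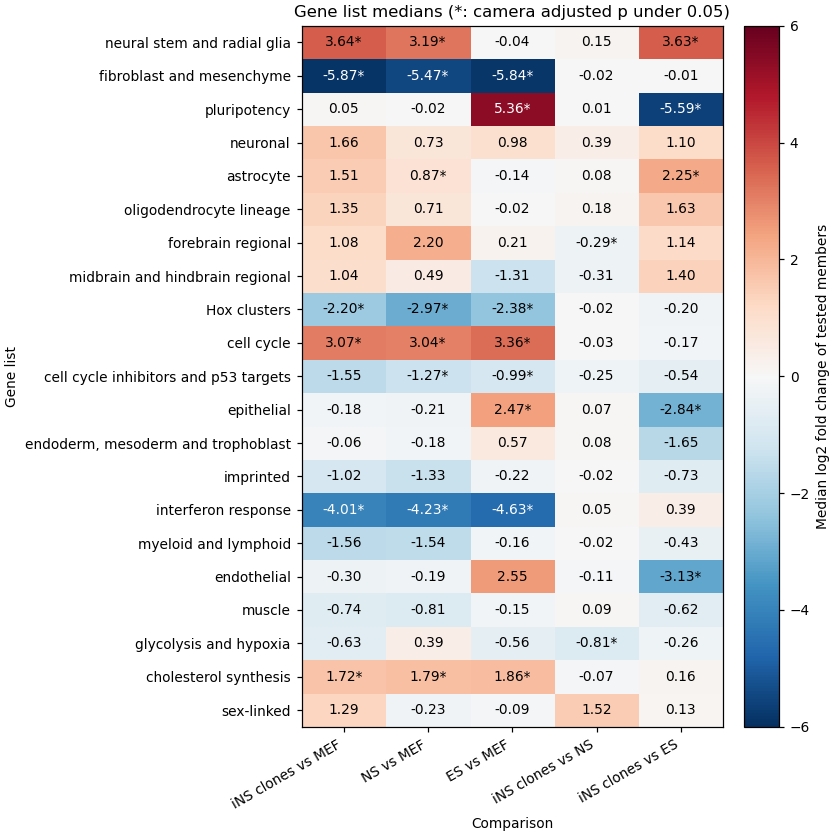
Median log2 fold change of the tested members of 21 gene lists (vertical axis) in 5 comparisons (horizontal axis), with a star where the camera adjusted p was under 0.05. The fibroblast list lies between -5.47 and -5.87 in NS, ES and the clones against MEF, and at -0.02 in the clones against NS.

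NS were set against MEF as the difference that a full conversion would cover. Olig1 was at least 532-fold higher in NS and not well above background in MEF (log2 difference 9.87 ± 0.13 SE, 3 against 4 arrays, limma adjusted p = 1.2e-21). Bcas1 and Rtn1 were at least 183-fold and 168-fold higher, and so was the brightest probe of Bex2, at least 251-fold, while another of its probes was above background in MEF. Chst7, Ednrb and Mest, measured on all arrays, were 74.5-fold, 60.3-fold and 59.4-fold higher. Bgn was at least 779-fold lower (log2 difference -10.55 ± 0.15 SE, adjusted p = 2.8e-21), Ccn2 at least 762-fold and Saa3 at least 723-fold, with NS not well above background. Ifitm3, an interferon-induced membrane protein, was 432-fold lower, Serpinf1 230-fold, the chemokine genes Ccl7 and Cxcl1 217-fold and 159-fold, Igfbp7 215-fold and Synpo 172-fold.

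Of the neural stem and radial glia list, 20 of 27 members were higher in NS, 3 lower and 4 not passing (21 and 3 adjusted over the list alone), with a median of 3.19, or 2.52 with bounds (camera adjusted p = 9.5e-06). All 34 fibroblast genes fell (34 adjusted over the list alone), with a median of -5.47, or -5.20 with bounds (camera adjusted p = 3.2e-16). Cell cycle genes rose in 23 of 26 cases (23 adjusted over the list alone, median 3.04, camera adjusted p = 4.3e-09), and all 25 interferon response genes fell (25 adjusted over the list alone, median -4.23, or -4.19 with bounds, camera adjusted p = 2e-11). Of the Hox clusters, 14 of 21 fell (15 adjusted over the list alone, median -2.97, or -2.29 with bounds, camera adjusted p = 6.3e-06), and 12 of 17 cholesterol synthesis genes rose (12 adjusted over the list alone, median 1.79, or 1.63 with bounds, camera adjusted p = 2e-04). These 6 calls held with an estimated correlation. Astrocyte genes had 7 members higher and 1 lower of 15 (7 and 1 adjusted over the list alone; camera adjusted p = 0.044, and adjusted p = 0.14 with an estimated correlation). Cell cycle inhibitors and p53 targets had 9 members lower and 3 higher of 17 (9 and 3 adjusted over the list alone; camera adjusted p = 0.023, and adjusted p = 0.065 with an estimated correlation). The median of the glycolysis and hypoxia list was 0.39 with a mean of 0.00, and camera did not call it.

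In all, 1725 genes were higher and 1828 lower in NS. In the single fits of each clone against MEF, 1807 genes rose and 1957 fell in iNS2, 1843 and 1871 in iNS3, and 1870 and 2036 in iNS5. With each array scaled to its median, the split in iNS5 was 2338 higher and 1587 lower. That scaling put the median log2 change of all genes against MEF at 0.30 in iNS5, 0.20 in iNS2, 0.15 in iNS3, 0.22 over the clones, 0.16 in NS and 0.13 in ES, and at -0.11 in iNS3 against iNS5. With quantile normalisation these medians lay between 0.04 and 0.08, and in the authors' scaled table the median of iNS3 was 0.12.

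Of the reprogramming genes, Sox2 was not well above background in MEF and was at least 22.9-fold higher in iNS2 (log2 difference 5.49 ± 0.08 SE, 3 against 4 arrays), 11.2-fold in iNS3 (4.46 ± 0.08 SE) and 27.2-fold in iNS5 (5.73 ± 0.08 SE, 4 against 4 arrays each), with adjusted p of 6.8e-19 or less. Klf4 was 12.6-fold, 10.2-fold and 6.01-fold lower than in MEF in the same order. Myc did not pass in any clone (log2 differences of 0.22, 0.22 and 0.28, SE 0.12 to 0.13). Pou5f1 was well above background on 1 array of each clone and 1 array of MEF, and Nanog on 1 array of iNS5 and on no other clone or MEF array.

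For the 3553 genes called between NS and MEF, the clones lay near NS. In iNS2, 97.24% of the genes were nearer to NS than to MEF (median position 1.01), in iNS3 95.78% (0.99) and in iNS5 95.61% (0.99), against 65.3% in ES (0.81). All 3 clones were nearer to NS for 3275 genes (92.18%), and none was for 40. Those 40 included Hoxa5, Neat1, Otx2, Sparcl1, Xist and Nap1l5, of which Neat1 was chosen after its values were seen (log2 level 11.03 in MEF, 7.36 in NS and 10.72, 11.01 and 10.50 in iNS2, iNS3 and iNS5). The calls of iNS2 against MEF shared 3198 genes in the same direction with those of NS against MEF, 90.01% of the NS calls, and 5 were opposite. iNS3 shared 3107 (6 opposite) and iNS5 3137 (7 opposite). Independent lists would share 640.7, 631.6 and 664.9, and lines simulated as unchanged against the same MEF arrays shared 0. An unchanged line has hardly any genes past the 2-fold test, so that 0 was close to fixed in advance. ES, too, lay nearer to NS than to MEF for 65.3% of these genes, and the overlap of ES calls with NS calls is not given. Overlaps above these baselines show a departure from MEF shared with NS, and not by themselves a likeness to NS. With the MEF arrays split between the comparisons the overlaps were 3036, 2940.5 and 2967.5. Across genes, log2 changes of the clones and of NS correlated at 0.962, 0.959 and 0.951, against 0.432, 0.461 and 0.463 in the simulated lines, and their covariance was 3.367, 3.304 and 3.31, against 0.0067, 0.0066 and 0.0067.

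**Figure D3:**
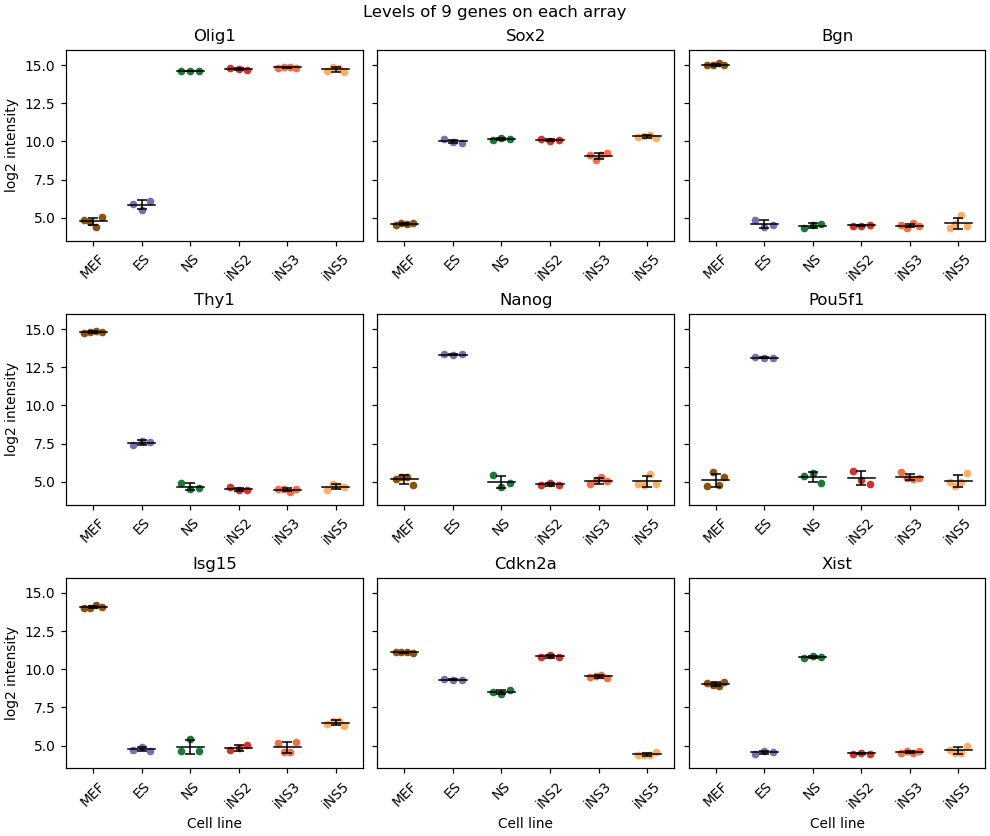
Log2 intensity of 9 genes on each array (points) in the 6 lines, with the mean and SD of each line as bars. Olig1 and Sox2 are high in NS and the clones, Bgn, Thy1 and Isg15 in MEF, Nanog and Pou5f1 in ES, while Cdkn2a is at 4.42 in iNS5 and Xist is at 4.58 over the clones.

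The clones were set against NS to ask where converted and forebrain-derived neural stem cells differ. Hoxa5, a homeobox gene of the neck and trunk, was at least 32.3-fold higher in the clones, with a log2 level of 10.43 on 11 of 11 clone arrays and no NS array well above background (log2 difference 6.08 ± 0.21 SE, limma adjusted p = 0.022). Eif2s3y, a gene of the Y chromosome, was 17-fold higher (log2 difference 4.08 ± 0.20 SE, adjusted p = 0.041). Xist, the RNA that silences an X chromosome, was at least 41.9-fold lower and not well above background on any clone array (log2 difference -6.20 ± 0.18 SE, adjusted p = 0.022). Eif2s3y and Xist are sex-linked, and source animals of different sex could give both differences. They are not read as effects of conversion, and the sex of the lines was not tested. Smim20 and Nap1l5 were at least 11.3-fold and 10.5-fold lower in the clones, and 1700048O20Rik, named after its values were seen, was the other lower gene. No other gene passed, and 607 genes had an unadjusted p under 0.05.

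The glycolysis and hypoxia list had median differences from NS of -1.37 in iNS2, -1.13 in iNS3 and -0.07 in iNS5, and neither the single clones nor their difference was tested. Over the clones its median was -0.81 over 21 members, with 0 members called (0 adjusted over the list alone). Camera called the list lower (adjusted p = 4.2e-07), but not with an estimated correlation (camera adjusted p = 0.51). The call was also lost with fry, a test that does not compare a list with other genes (fry adjusted p = 0.332). The estimated correlation of this list was 0.671, above the preset value, so the p-value of 4.2e-07 from camera may be too small. P4ha2, whose brightest probe was above background on 4 of 11 clone arrays, had a log2 difference of -2.25 ± 0.83 SE, and Ndrg1, above background on 5, one of -1.98 ± 1.09 SE. Both differences are taken partly against background, and the true ones may be smaller. The forebrain list was called lower, with a median of -0.29 over 5 members (camera adjusted p = 0.042, and adjusted p = 0.45 with an estimated correlation). That call was also lost without background correction (adjusted p = 0.138), with an offset of 50 (0.072), with the slide as a fixed block (0.119) and in the authors' scaled table (0.0618). Otx2, a forebrain and midbrain homeobox gene, passed only when adjusted over the list alone, at least 2.54-fold lower (SE 0.16) and with no clone array above background. Of 21 Hox genes, 1 passed over all genes, and 4 higher and 1 lower passed adjusted over the list alone. Those 5 were Hoxa5, Hoxa4 (at least 2.7-fold higher, SE 0.18), Hoxa2 (at least 1.87-fold, SE 0.34), Hoxa7 (at least 2.89-fold, SE 0.47) and, lower and on no clone array above background, Hoxd11 (SE 0.18). Of the 4 HoxA genes only Hoxa4 was well above background on an NS array, and on 1. The Hox median was -0.02 and its mean 0.49.

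Of the 27 neural stem and radial glia genes, 0 passed (0 adjusted over the list alone), with a median of 0.15, and Pou3f4 had the largest difference (1.32 ± 0.61 SE). Of the 34 fibroblast genes, 0 passed (0 adjusted over the list alone), with a median of -0.02 and a mean of -0.25. The list was not called (camera adjusted p = 0.22), but with each array scaled to its median it was called lower (camera adjusted p = 0.0285). Ccdc80 stood at -2.65 ± 0.57 SE with 8 of 11 clone arrays above background, a difference taken partly against background. Of the sex-linked genes, Eif2s3y and Xist passed, and 3 higher and 1 lower passed adjusted over the list alone. Of the endothelial genes 1 passed adjusted over the list alone, Emcn, at least 2.05-fold lower (SE 0.30) and with no clone array above background. Medians, means and test direction differed in sign, with no call, for the midbrain and hindbrain (median -0.31, test up), pluripotency (median 0.01, mean 0.00), cell cycle (-0.03, 0.00), endothelial (-0.11, 0.08) and cholesterol synthesis (-0.07, 0.01) lists.

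The comparison with NS rests on 3 clones against 1 line, and the same fit made 4 false calls on simulated data, against the 6 genes called here. Leaving out any 1 clone left 0 genes, while treating arrays as replicates gave 200 (81 higher, 119 lower) and the authors' scaled table gave 14, all lower. The split of higher and lower genes was 0 and 1 without background correction, 2 and 7 without the detection filter and 1 and 4 with an offset of 50.

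**Figure D4:**
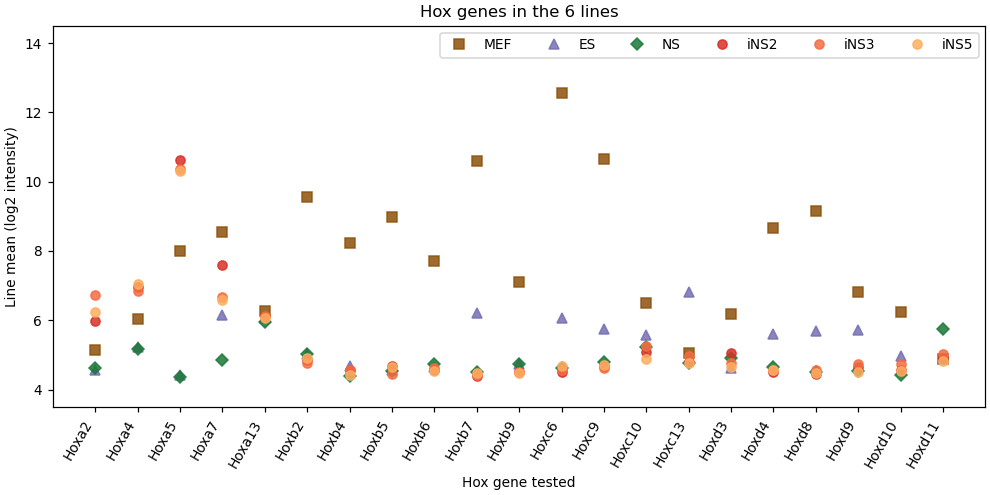
Mean log2 intensity of 21 Hox genes in the 6 lines. In the clones, Hoxa2, Hoxa4, Hoxa5 and Hoxa7 lie above NS by at least 1.87-fold, 2.7-fold, 32.3-fold and 2.89-fold, and the 16 tested genes of the B, C and D clusters are not well above background on any clone array.

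The clones were also set against one another. Against iNS3, iNS2 had 55.6-fold more Ifitm3 (log2 difference 5.80 ± 0.09 SE, 3 against 4 arrays, limma adjusted p = 3.5e-18), 20.3-fold more Ramp1 and 12.6-fold more Ifitm1. The stress gene Ddit4l and the protease gene Ctsc were at least 50.4-fold and 36.2-fold higher in iNS2 and not well above background in iNS3. Ctse, Acsl5 and Slc24a3 were 13-fold, 10.2-fold and 8.54-fold lower in iNS2. Mcts1 and the imprinted gene Ndn were at least 33.4-fold and 18.6-fold lower there and not well above background. Between iNS2 and iNS3, 36 genes were higher and 63 lower, or 24 and 27 without background correction.

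Against iNS5, iNS2 had 17.6-fold more smooth muscle actin Acta2 (log2 difference 4.14 ± 0.06 SE, 3 against 4 arrays, adjusted p = 8.3e-19), 10.1-fold more Ilvbl and 9.17-fold more Ifitm3. Lxn and Cdkn2a, which encodes inhibitors of the cell cycle, were at least 93.8-fold and 45.5-fold higher in iNS2 and not well above background in iNS5. Mmd2, Acsl5 and Mmp14 were 30.6-fold, 21.4-fold and 11.9-fold lower in iNS2, and Mcts1 and the DNA sensor gene Cgas at least 44.7-fold and 25.4-fold. Between these clones 65 genes were higher and 148 lower in iNS2, or 41 and 164 with median scaling, and 114 in all with the slide as a fixed block. As iNS2 and iNS5 shared no slide, line and slide can be told apart here only through iNS3, whose replicate 4 lay on a slide with iNS5.

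Against iNS5, iNS3 had 9.35-fold more Ilvbl (log2 difference 3.23 ± 0.07 SE, 4 against 4 arrays, adjusted p = 8.6e-15), 7.12-fold more Bmper and 5.67-fold more Pcp4l1. Lxn and Cdkn2a were at least 52.2-fold and 18.4-fold higher in iNS3. Ramp1, Mmd2 and the collagen gene Col18a1 were 19.6-fold, 16.3-fold and 15.7-fold lower in iNS3, Ddit4l and Csmd2 at least 52.3-fold and 26.9-fold, and the brightest probe of Sox2 2.42-fold (adjusted p = 0.031). The other probe of Sox2 that passed the detection filter showed no such difference (0.07 on the log2 scale). Between these clones 171 genes were higher and 233 lower in iNS3, or 84 and 308 with median scaling. With the slide as a fixed block 193 genes passed, and on the slide both shared, with 1 array each and no test, 966 genes were 2-fold apart. Each pair of clones was compared with technical spread alone.

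The clones were set against ES to ask how far they differ from pluripotent cells. Pluripotency genes were lower: Tfcp2l1 and Zfp42 were at least 264-fold and 138-fold lower and not well above background on any clone array. Dppa5a was at least 705-fold lower with 4 of 11 clone arrays above background, and Nanog at least 242-fold lower with 1 (11 arrays of 3 clones against 3 ES arrays, limma adjusted p = 0.00047). Pou5f1 was at least 202-fold lower with 3 clone arrays above background, and Klf4 15.8-fold lower. Sox2 did not differ by the test (log2 difference -0.18 ± 0.56 SE). Olig1 was 485-fold higher in the clones, Slc1a3 303-fold, Ednrb and Tnc at least 182-fold and 158-fold, and Ptn, a secreted growth factor, at least 460-fold.

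Of 32 pluripotency genes, 31 fell (31 adjusted over the list alone), with a median of -5.59, or -5.02 with bounds (camera adjusted p = 6.7e-17, and adjusted p = 0.13 with an estimated correlation). Of 27 neural stem and radial glia genes, 22 rose (22 adjusted over the list alone), with a median of 3.63, or 3.26 with bounds (camera adjusted p = 1.1e-09, and adjusted p = 0.11 with an estimated correlation). All 14 epithelial genes fell (14 adjusted over the list alone), with a median of -2.84, or -2.27 with bounds (camera adjusted p = 2.3e-08, and adjusted p = 0.13 with an estimated correlation). Spint1 and Cldn4 were at least 86.6-fold and 63.1-fold lower, and Cdh1, the adhesion molecule of epithelia, at least 51.3-fold with 1 of 11 clone arrays above background. Astrocyte genes were higher in 9 of 15 cases and lower in 1 (11 and 1 adjusted over the list alone; camera adjusted p = 0.00082, and adjusted p = 0.45 with an estimated correlation). Endothelial genes fell in 5 of 7 cases (5 adjusted over the list alone; camera adjusted p = 0.043, and adjusted p = 0.45 with an estimated correlation), with Pecam1 and Vwf at least 11.7-fold and 8.88-fold lower. The fibroblast list was not called, with a median of -0.01 and a mean of 0.07. In all, 2248 genes rose and 2349 fell against ES, and without clone 2 the total of 4597 became 2372.

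ES were set against MEF as the background comparison. Dppa5a was at least 676-fold higher in ES and not well above background in MEF (log2 difference 10.04 ± 0.13 SE, 3 against 4 arrays, limma adjusted p = 1.5e-21). Tfcp2l1, Esrrb and Nanog were at least 234-fold, 218-fold and 217-fold higher. The glucose transporter gene Slc2a3 was 165-fold higher, Laptm5 84.9-fold and Mybl2 68.5-fold. Tnc, Bgn and Saa3 were at least 806-fold, 783-fold and 727-fold lower and not well above background in ES, and Acta2 was 425-fold lower. Pluripotency genes rose in 29 of 32 cases (29 adjusted over the list alone, median 5.36, or 4.63 with bounds, camera adjusted p = 5.9e-10), and all 34 fibroblast genes fell (34 adjusted over the list alone, median -5.84, camera adjusted p = 9.6e-14). Interferon response genes fell in 24 of 25 cases (24 adjusted over the list alone, camera adjusted p = 2.5e-09), cell cycle genes rose in 23 of 26 (23 adjusted over the list alone, camera adjusted p = 1.8e-08), epithelial genes in 12 of 14 (12 adjusted over the list alone, camera adjusted p = 0.0013), and 13 of 21 Hox genes fell (13 adjusted over the list alone, camera adjusted p = 2.4e-04). Those 6 calls held with an estimated correlation. Cholesterol synthesis genes rose in 11 of 17 cases (11 adjusted over the list alone; camera adjusted p = 0.0027, and adjusted p = 0.062 with an estimated correlation). Cell cycle inhibitors and p53 targets fell in 7 of 17 and rose in 1 (7 and 1 adjusted over the list alone; camera adjusted p = 0.023, and adjusted p = 0.065 with an estimated correlation). The myeloid and lymphoid list, not called, had a median of -0.16 and a mean of 0.95. In all, 2302 genes were higher in ES and 2387 lower.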

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

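The tests of the HoxA genes, of Cdkn2a on a shared slide, of Xist, of values without background correction and of the other splits of the arrays were chosen only after the result was seen, and those of Mtap, the shared slide of NS and the authors' scaled values were fixed before. The HoxA slide and fibroblast tests first ran on only the 4 HoxA genes above NS, and widening them to all 5 left that choice largely in place. The Xist test replaced one on 4 genes that no clone array held, of which Xist is one.

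In lines with 4 arrays, an array stood far from the other arrays of its line in 27 of 468 groups of values, or 5.77%, where chance gives about 1 in 20. The number that follows each gene is the gap to the nearest array as a share of the range of the 4 arrays. In MEF, these were Chst7 (0.943) and Nfia (0.843) on replicate 1, Tnc (0.907) and Apoe (0.84) on replicate 2, and Mcm5 (0.876), Ifitm3 (0.863) and Ifit2 (0.876) on replicate 3. On MEF replicate 4 they were Coro1a (0.852), Igfbp7 (0.861) and Esrp2 (0.83). In iNS3, they were Pou5f1 (0.88) and Top2a (0.904) on replicate 1, Myc (0.941), Dlx1 (0.946) and Fgfr3 (0.957) on replicate 3, and Gap43 (0.935) and Nfia (0.976) on replicate 4. In iNS5, they were Otx1 (0.961) and Ccdc80 (0.899) on replicate 1, Id3 (0.913), Peg3 (0.847) and Osmr (0.931) on replicate 4, and Dppa5a (0.848), Nanog (0.924), Nsdhl (0.845), Mcts1 (0.851) and Fbln2 (0.898) on replicate 3.

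The clones differed from one another by the limma test of each difference. Between iNS2 and iNS3, 99 genes differed, among them Ddit4l (6.35 on the log2 scale), Ctsc (6.25), Ifitm3 (5.80), Ramp1 (4.34) and Ifitm1 (3.66), higher in iNS2, and Mcts1 (-5.88), Ndn (-5.07), Ctse (-3.70), Acsl5 (-3.35) and Slc24a3 (-3.09), lower there. Between iNS2 and iNS5, 213 genes differed, among them Lxn (6.69), Cdkn2a (6.42), Acta2 (4.14), Ilvbl (3.34) and Ifitm3 (3.20), higher in iNS2, and Mcts1 (-6.30), Cgas (-5.43), Mmd2 (-4.94), Acsl5 (-4.42) and Mmp14 (-3.58), lower there. Between iNS3 and iNS5, 404 genes differed, among them Lxn (5.84), Cdkn2a (5.12), Ilvbl (3.23), Bmper (2.83) and Pcp4l1 (2.50), higher in iNS3, and Ddit4l (-6.40), Csmd2 (-5.81), Ramp1 (-4.29), Mmd2 (-4.03), Col18a1 (-3.98) and Sox2 (-1.28), lower there. The value of Sox2 is that of its brightest probe, and its other probe that passed the detection filter was at 0.07. Where one clone of a pair was not well above background (Ddit4l, Ctsc, Mcts1, Ndn, Lxn, Cdkn2a, Cgas and Csmd2), the difference is taken against background, and only the at least folds given with the pairs hold. Outside the genes, 2553 probes without a single gene symbol were well above background on every array of at least 1 line, and in NS against MEF 431 of them were higher and 351 lower.

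For each comparison of lines, the 7 or 8 arrays were split into groups of the same sizes in every other way, and only 1 of 35 splits, the real one, gave as many genes. A split that mixes unlike lines raises the spread within its groups, so this outcome was close to fixed in advance. The arrays of a line are technical replicates, and the splits say nothing about spread between lines. Where the lines compared shared no slide (ES with MEF, iNS2 with MEF and iNS2 with iNS5), the splits cannot tell line from slide. The real count was 4689 in ES against MEF, with 675 in the highest other split, and 3764 in iNS2 against MEF, with 536. In both cases that split set the 3 MEF arrays of one slide against MEF replicate 4 together with the other line, so it kept most of the real grouping. In NS, iNS3 and iNS5 against MEF the real counts were 3553, 3714 and 3906, in the pairs of clones they were 99, 213 and 404, and the highest other split gave 0.

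The first pattern was that 4 of 5 tested HoxA genes lay at least 1.87-fold above NS in the clones, while the 16 tested genes of the other Hox clusters were not well above background on any clone array. Fibroblasts left in the clone cultures would bring all their abundant transcripts, but the fibroblast list kept a median of 1.05% of its MEF signal in the clones, and at most 1.64% with dim arrays at their bound, against 218% for the 5 HoxA genes. A slide effect would be missing on the slide of NS, where iNS3 and iNS5 lay above NS by a median of 1.87 on the log2 scale over the 5 HoxA genes, or at least 1.27 with NS at its bound, and Hoxa4, Hoxa5 and Hoxa7, the 3 picked on clone arrays of other slides alone, lay above the same NS arrays by a median of at least 1.53 and each by at least 1.15. The Hox pattern of the fibroblasts was not kept whole, since the other clusters had a median difference from MEF of -3.42, or -2.58 with the clones at their bound, which describes the pattern and is no separate test of it. Against MEF the HoxA genes went both ways. The log2 difference of the clones was 2.44 for Hoxa5, 1.17 for Hoxa2, 0.92 for Hoxa4, -0.17 for Hoxa13 and -1.59 for Hoxa7. Hoxa5, the 1 Hox gene called against NS, thus lay above its MEF level. A HoxA activity that arose or was kept during conversion, or a difference in regional identity between the clones and forebrain NS, may account for it, and neither was tested.

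The second pattern was that Cdkn2a and Cdkn2b were not well above background on any of the 4 iNS5 arrays, with log2 levels of 4.42 and 4.48, against 10.84 and 7.80 in iNS2 and 9.53 and 5.94 in iNS3. A failed array or slide does not account for it, since on the slide both clones share Cdkn2a was at -5.04 on the log2 scale in iNS5 against iNS3, a difference taken against background, and at least 17.2-fold lower. A loss that also took both copies of the neighbouring gene Mtap would leave Mtap at background. Mtap stood 1.26 higher on the log2 scale in iNS5 than in the mean of iNS2 and iNS3 and was well above background on all 4 iNS5 arrays. The prediction set before had also bounded Mtap from above at 2-fold. That upper bound was wrong, because a loss of both copies forbids a detected Mtap at any level, and it was dropped after the value was seen. A loss of Mtap on 1 copy alone would leave Mtap detected, so these values cannot decide on it. A smaller loss that spares Mtap, or silencing of Cdkn2a and Cdkn2b, may account for it, and neither was tested.

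The third pattern was that the clones lay close to NS. RNA of NS on the clone arrays would bring every bright NS transcript in the same share, but Xist, chosen because it was missing, kept 0.456% of its NS signal, and at most 1.49% with the clones at their bound, and the other 3 missing genes at most 5.67% to 6.52%. A shared slide would raise the correlation with NS, and the largest gain from sharing it was 0.0023 among MEF, iNS3 and iNS5. The quantile step would be at work if the closeness were missing from the authors' scaled values, where the lowest correlation of a clone with NS was 0.968 and the highest with MEF or ES 0.733; that table has background subtracted, and for the background step the values without correction gave 0.976 and 0.79. A neural stem cell state of the clones is consistent with these values as a hypothesis, since it was found and tested on the same arrays and on 1 NS line.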

How the results depend on the processing

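The alternative that keeps only the slide holding NS, with clones 3 and 5, was chosen only after the result was seen; all others were fixed in advance. Named genes kept direction and side of the threshold in 7640 of 7920 recalculations of 464 results (252 lost and 27 gained the call, 1 reversed), and lists in 865 of 945 of 105 results (28 lost, 49 gained, 3 reversed). Most named genes were picked from these data for large changes or high levels, so their stability follows in part from that choice. It does not describe all genes, whose counts are given below. Ccng1 in ES against MEF reversed, at 0.18, with the mean of all probes. With fry, which does not compare a list with other genes, the direction reversed for the forebrain list in the clones against ES (adjusted p = 0.0204) and for the sex-linked list against MEF (0.0359) and NS (0.0309). Of 105 list tests, 29 were called, 12 with an estimated correlation and 77 with fry. The 12 were all in NS or ES against MEF. In the clone comparisons 0 were called, where the estimated form has 2 degrees of freedom. Signal over background limits genes that are dim in all lines, and leaving background in shrinks folds. Except where a construction is named, the cause was not tested.

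Without background correction, which shrinks folds, the counts were 3025 (ES), 2219 (NS), 2367 (iNS2), 2328 (iNS3) and 2422 (iNS5) against MEF, 51, 96 and 152 for iNS2 with iNS3, iNS2 with iNS5 and iNS3 with iNS5, and 1 for the clones against NS. Overlaps with NS were 2012, 1942 and 1953 (iNS2, iNS3, iNS5), and shares nearer to NS 68.72% (ES), 97.43% (iNS3) and 96.62% (iNS5). Tested against no change in place of 2-fold, the counts were 9025, 8492, 8616, 8664 and 8858 in the same order, the clone pairs 3823, 4548 and 6229, and the overlaps 7703, 7549 and 7691. An adjusted p against no change with a 2-fold change gave 302, 436 and 857 for the pairs. The slide as a fixed block gave 114 for iNS2 with iNS5 and 193 for iNS3 with iNS5, and 966 genes were 2-fold apart on the slide iNS3 and iNS5 share, 1 array each. An offset of 50 gave 269 for iNS3 with iNS5 and shares of 96.75% (iNS3) and 96.27% (iNS5). In the authors' scaled table the clones against NS gave 14, and the shares were 96.53% (iNS2) and 94.93% (iNS3). Among genes at least 4-fold apart, the shares were 97.68% (iNS3) and 96.8% (iNS5).

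Arrays as replicates gave 200 for the clones against NS. Only the slide of NS gave 0 there, with fewer arrays and limma, and 2727 against MEF. Leaving out 1 clone gave 2372 to 5148 against ES and 2719 to 5429 against MEF, both lowest without clone 2, and 0 to 0 against NS, where fewer clones were left. Leaving out 1 array gave 4568 to 4676 (ES), 3431 to 3537 (NS), 3650 to 3786 (iNS2), 3633 to 3732 (iNS3) and 3832 to 3908 (iNS5) against MEF, 89 to 97, 196 to 208 and 372 to 390 for the pairs, and shares of 65% to 65.64% (ES), 97.06% to 97.33% (iNS2), 95.6% to 95.97% (iNS3) and 95.48% to 95.79% (iNS5).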

Other observations

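No test in this part was fixed before the result was seen, and the genes named here were chosen after their values were seen. A set of 11 genes was well above background on all 11 clone arrays and on no array of MEF, NS or ES. Among them Myt1, a zinc finger factor of neural progenitors, had log2 levels of 8.57, 8.66 and 8.86 in iNS2, iNS3 and iNS5 against 5.05 in NS, and Slc1a2, a glial glutamate transporter, 6.32, 6.54 and 7.92 against 5.08. Cyp3a13 had 6.94, 6.85 and 6.07 against 4.77, and Foxd2os 6.44, 6.49 and 6.65 against 4.56. In the other direction, 27 genes were well above background on every MEF and NS array and on no clone array, and 16 of these were so on every ES array. Gas6, a ligand of receptor tyrosine kinases, had 13.74 in MEF, 7.79 in NS and 8.21 in ES, against 4.57, 4.73 and 4.67 in iNS2, iNS3 and iNS5. S100a6 had 12.31, 6.42 and 10.75 against 4.63, 4.77 and 4.67, and Ctsz, a lysosomal protease, 10.51, 7.38 and 7.96 against 4.64, 4.60 and 4.52. None of the genes named in this paragraph was among the 6 called in the test of the clones against NS. No like count for another line is given beside the 11 and the 27.

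Single clones lacked or had genes that the other clones did not share. The imprinted gene Ndn had a log2 level of 4.55 ± 0.06 (SD, n = 3 arrays) in iNS2, where it was not well above background, against 9.62 ± 0.05 in iNS3, 8.92 ± 0.10 in iNS5 (n = 4 each) and 10.37 ± 0.02 in NS (n = 3). Nnat, also imprinted, had 4.47 ± 0.10 in iNS2, against 8.48 ± 0.09, 9.60 ± 0.09 and 9.09 ± 0.22. En2, a midbrain and hindbrain factor, had 4.90 ± 0.12 in iNS2, against 7.42 ± 0.09, 7.61 ± 0.21 and 8.72 ± 0.07. Gpr17, a receptor of oligodendrocyte precursors, had 7.74 ± 0.11 in iNS2, against 4.52 ± 0.07, 5.10 ± 0.39 and 4.48 ± 0.06, and besides the iNS2 arrays it was well above background on 1 array of iNS5.

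The median difference from NS over 21 glycolysis and hypoxia genes was -1.37 in iNS2 and -1.13 in iNS3, with 12 genes over 2-fold lower in each, and -0.07 in iNS5, with 2. It was -0.39 in MEF and -0.37 in ES. Xist had a log2 level of 9.03 ± 0.11 (SD) in MEF and 10.78 ± 0.07 in NS and was not well above background in ES or the clones. Eif2s3y had 7.74 ± 0.30 in MEF, 6.09 ± 0.04 in NS, 10.93 ± 0.07 in ES and 10.20 ± 0.12, 10.32 ± 0.27 and 10.02 ± 0.21 in iNS2, iNS3 and iNS5. Kdm5d was well above background on all clone arrays and on no array of MEF, NS or ES. Per chromosome, the median differences of iNS3 from the mean of the other clones were highest on chromosomes 5 and 8, at 0.11 each, and the median of iNS5, taken the same way, was lowest on chromosome 11, at -0.12.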
